A study of Mus musculus with 6 samples.

How the data were processed

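The samples were 3 pairs of poly(A)-selected RNA libraries from preoptic area tissue of NuTRAP mice crossed to Pnoc-Cre, in which Cre-expressing cells carry EGFP on the ribosomal protein L10a. Per the labels' protocols, tagged ribosomes were bound to magnetic beads carrying an antibody against GFP, and the RNA extracted from them gave the IP libraries. Total RNA of the tissue gave the input libraries. Libraries were sequenced as paired ends of 75 bp on a NovaSeq X Plus. Reads were aligned with HISAT2 to mm39, counted with featureCounts and compared with DESeq2, per the submitters' processing notes, with versions not given in the sources used here. Whether counting used strand is not given there either, so that reads of overlapping and antisense genes may be shared.

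The deposited table holds 27884 genes. Its read counts per gene were made by the authors and are whole numbers without normalization, and every gene in the table has at least 2 counts in total. Its second block of values, a normalized signal, was made by the authors by dividing the counts by 1 size factor per library, which was checked to be constant over genes within a tolerance of 1e-06. Its FPKM values were made by the authors from the counts and a gene length. The authors' log2 fold changes and p-values come from DESeq2, per the file headers and the submitters' processing notes. An adjusted p of 1 stands in the authors' deposited table for 5432 genes, of which 26 have no p. The authors' deposited table calls 2883 genes higher and 3759 lower in IP at an adjusted p under 0.05. Of the genes called here 5543 are called there with the same sign. Coordinates are those of the table, on mm39. Of its gene identifiers 27576 were found in GENCODE M39, all on the same chromosome with overlapping spans. Of the gene symbols 69 extra entries repeat a symbol.

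Only the counts entered the tests. Groups and replicate numbers came from the sample titles. The main test, fixed before the data were examined, was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter by group, group as the one factor and Benjamini-Hochberg adjustment, two-sided, with an adjusted p under 0.05 as the threshold. After the filter 18640 genes were tested. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. A count of 3 corresponds to 0.06 CPM in input replicate 1. Reads carry no molecular identifiers, and depth was alike in the 6 libraries.

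The same-numbered IP and input libraries come from the same pool of tissue, since the series' design text states that input was taken from each sample processed in parallel, and they are therefore paired. The main test has no term for the pairing. Deviations from the group means in log2 CPM correlated at 0.26, 0.14 and 0.10 between same-numbered libraries of replicates 1, 2 and 3, and between -0.22 and 0.09 between libraries of different numbers. A fit with the replicate as a block was an alternative. Its values stand beside a result where it changes a call or moves a count by more than 1.5 times. Replicates are pools of 3 animals, so that the spread between pools is smaller than that between animals. Spearman correlations of log2 CPM within groups lay between 0.964 and 0.984.

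Lists of cell-type markers, peptides, receptors, channels and RNA classes were written before the data were examined and tested with limma's camera on voom values (limma 3.58.1, preset correlation 0.01, lists with at least 3 tested members, 36 lists, Benjamini-Hochberg over lists), with an estimated correlation and with fry beside it. Named genes follow a rule fixed in advance. It takes Pnoc; the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with non-overlapping groups and a mean of at least 3 log2 CPM; in each list the 2 smallest adjusted p in each direction, or the 2 most abundant members where none passed; any peptide, thermoregulatory marker, hormone receptor or opioid receptor; and the 5 smallest adjusted p in each direction. The rule covered 201 genes, of which 115 were called and 80 kept the call without any one library. Gad1, Gad2, Slc32a1, Slc17a6, Slc17a7, Map2, Rbfox1, Arc, Npas4, Nr4a1, Homer1, Egr3, Kcne2, Fezf2, Neurod2, Neurod6, Hmox1, Tshz2, Ttr and Tnnt1 were named outside the rule, after their values were seen. Values of some single genes are not reported here.

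Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a stricter filter of at least 1 CPM in all libraries of a group, the replicate block, each library left out and a test against a fold change of 1.5. Added after seeing the data were library totals alone as the scaling, both libraries of a replicate left out, and a correction of each library for transcript length and GC content with splines of 4 degrees of freedom, with the mean change either kept or set to 0. For named genes the upper-quartile, filter and left-out-library settings were also added after seeing the data. Length and GC came from the Ensembl canonical transcript in GENCODE M39, and 99.9% of the protein-coding genes tested had a value. On simulated counts for 18640 genes, with 200 changed, edgeR called 16%, 44%, 90% and 94% of the genes changed by 1.5, 2, 4 and 8-fold with the right sign and 13 unchanged genes. DESeq2 called 36%, 68%, 94% and 100% of them and 52 unchanged genes. The simulation had no pairing of pools and far fewer changed genes than were called in the data. The adjusted threshold depends on that number, so these rates do not carry over to the data.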

Results

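Poly(A)-selected RNA was sequenced from the preoptic area (POA) of the hypothalamus, a region that controls body temperature and energy use, of mice in which Pnoc-Cre switches on an EGFP tag on the ribosomal protein L10a. Pnoc encodes prepronociceptin, the precursor of the peptide nociceptin. In each of 3 replicates, ribosome-bound RNA purified with an antibody against GFP (IP) was sequenced beside the total RNA of the tissue processed in parallel (input), so that 3 IP and 3 input libraries were compared. Each replicate pooled the tissue of 3 females aged 17 to 18 weeks. Total counts ran from 48204567 to 51380354 in the IP libraries and from 49068467 to 53056642 in the input libraries. The comparison asks which transcripts the tagged PNOC cells of this region carry on their ribosomes relative to the whole tissue, in a study of how medial preoptic PNOC neurons restrain heat production in brown fat.

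Pnoc itself was higher in IP in all 3 replicates, which checks the labels of the libraries. The gene (ENSMUSG00000045731, chromosome 14, 65638122 to 65662921, minus strand, mm39) had 44.0 ± 3.39 CPM (counts scaled by library size; SD, n = 3) in IP against 10.6 ± 2.88 CPM (SD, n = 3) in input. The IP libraries held from 41.1 to 47.7 CPM and the input libraries from 7.51 to 13.2 CPM. The log2 fold change was 2.06 ± 0.22 (SE), a 4.16-fold difference, with an adjusted p of 0.000472 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Left out one at a time, the 6 libraries gave log2 fold changes between 1.87 and 2.28, and the call was kept each time.

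Among the preset lists, neuropeptide genes had the highest median log2 fold change and mitochondrial, oligodendrocyte and microglial transcripts the lowest. After correction for transcript length and GC with the replicate as a block, the neuropeptide median was 0.54, near the pan-neuronal median of 0.51. Of 13 GABAergic markers 5, of 15 pan-neuronal genes 6 and of 38 peptide precursor genes 12 rose in IP. Markers of astrocytes, oligodendrocytes, microglia and blood and the transcripts of the mitochondrial genome fell. Of 18640 genes tested with edgeR's quasi-likelihood test, 2400 were higher and 3191 lower in IP at an adjusted p under 0.05. Among them 553 were higher by at least 2-fold and 2276 lower by at least 2-fold, and 36 were higher and 1262 lower by at least 4-fold. The 3 IP libraries all lay on one side of the 3 input libraries for 8893 genes, or 47.7% of those tested. With library totals alone as the scaling, 1734 genes were higher and 3678 lower; with TMM scaling, used for all values given here, higher genes made up 42.9% of the calls. With a length and GC correction that also sets the mean change to 0 the balance turned, with 4620 genes higher and 2326 lower. The number of higher genes depended on single libraries, being 1445 without input replicate 3, 1479 without IP replicate 2 and 1417 without IP replicate 3, and the number of lower genes was 2035 without input replicate 3. Without both libraries of replicate 1, a pool that differed from the others, 2041 genes were higher and 2808 lower. These counts were 1508 and 2095 without both libraries of replicate 2, and 133 and 742 without both libraries of replicate 3. Gene lists fixed before the data were examined were also tested as a whole with limma's camera. Of 36 lists 16 passed at its preset correlation and 0 with an estimated correlation (6 at an unadjusted p under 0.05; fry, a test of each list on its own, called 13), and other divisions of the same 6 libraries into 3 and 3 gave up to 19 calls at the preset correlation. Each of those other divisions holds both kinds of library on each side in unequal number. They keep part of the difference between IP and input, and so do not show how often camera calls lists without one. That 0 lists passed with an estimated correlation cannot be put down to correlation between genes alone. The estimate was -0.015 for oligodendrocyte precursor markers and -0.074 for nuclear long RNAs, both below the preset 0.01. Their camera adjusted p still rose from 4.45e-05 to 0.17 and from 0.000369 to 0.18. For other lists the estimate lay above the preset, as for striatal markers at 0.88. The 0 is therefore not taken as evidence against a list, and the counts of genes per list come first here.

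**Figure D1:**
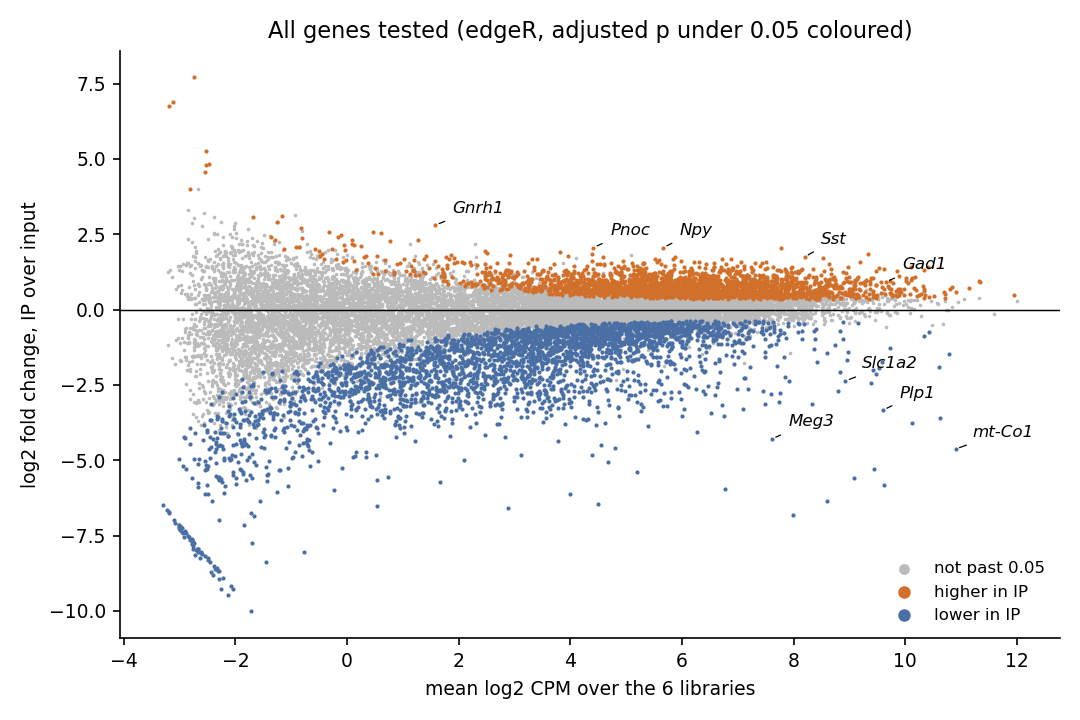
Each point is one of the 18640 genes tested, with the mean log2 CPM over the 6 libraries on the horizontal axis and the log2 fold change of IP over input on the vertical axis. The 2400 genes higher and the 3191 genes lower in IP are coloured, and the line of points at the lower left holds genes without a count in any IP library, which were 60 of the lower genes.

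Glial markers were far lower in IP than in input. All 13 astrocyte markers tested fell, with a median log2 fold change of -2.65, as did all 12 oligodendrocyte markers, with a median of -3.21, and all 13 microglial markers, with a median of -3.04. Aqp4, the water channel of astrocyte endfeet, stood at -3.53 ± 0.16 (SE) on the log2 scale, an 11.5-fold difference. Mal, a myelin protein gene on chromosome 2 from 127475146 to 127498615, had 27.9 ± 2.40 against 303 ± 23.0 CPM (SD, n = 3), a 10.9-fold difference. Csf1r, the growth factor receptor that microglia depend on, had 3.40 ± 0.83 against 41.3 ± 0.72 CPM (SD, n = 3), a 12.1-fold difference. In edgeR's test the adjusted p was 1.76e-05 for Aqp4 and Mal and 3.29e-05 for Csf1r. Of 9 oligodendrocyte precursor markers 7 fell, with a median of -2.92, among them Pdgfra at -3.58 ± 0.20 (SE) and Gpr17 at -3.04 ± 0.24 (SE). The counts adjusted over the list alone were the same for these 4 lists, 13, 12, 13 and 7. With limma's camera at its preset correlation the adjusted p was 3.66e-12 for astrocyte, 2.39e-13 for oligodendrocyte, 9.13e-10 for microglial and 4.45e-05 for precursor markers. With an estimated correlation none of the 4 passed, with an adjusted p = 0.17 for astrocyte, 0.26 for oligodendrocyte, 0.20 for microglial and 0.17 for precursor markers.

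Vessel, blood and ventricle markers were lower in part. All 5 blood genes fell, with a median log2 fold change of -2.92, among them the haemoglobin gene Hba-a1 at -2.96 ± 0.27 (SE). Its near-identical copies can share reads, so that this value is uncertain. Of 11 endothelial markers 7 fell, with a median of -2.16, of 9 mural cell markers 5 fell, with a median of -2.20, and of 7 leptomeningeal fibroblast markers 4 fell, with a median of -2.03. Cldn5, a tight junction gene, stood at -2.16 ± 0.36 (SE), and Rgs5, a pericyte gene, at -2.08 ± 0.19 (SE). Of 8 ependymal markers 4 fell, or 7 after length and GC correction with the replicate block, including Foxj1, the regulator of motile cilia, at -1.49 ± 0.28 (SE, without correction). Of 8 tanycyte markers 2 fell, among them Vim at -1.45 ± 0.28 (SE). Of 8 choroid plexus markers 1 fell, Clic6, at -1.65 ± 0.53 (SE), and 0 in DESeq2. The lower counts adjusted over the list alone were 5 for blood, 8 for endothelial, 5 for mural, 4 for leptomeningeal, 4 for ependymal, 2 for tanycyte and 0 for choroid plexus markers. With the replicate as a block, 3 choroid plexus markers fell (Clic6, Kcne2 and Ttr) and that list's camera adjusted p was 0.0231, against 0.57 without the block and 0.87 with an estimated correlation. Without 1 library the endothelial count fell to 4 (IP replicate 3), the leptomeningeal count to 2 (input replicate 3), and the ependymal count to 1 (input replicate 3 or any one of the IP libraries). Clic6 lost its call after length and GC correction (adjusted p = 0.054, edgeR), without input replicate 1 or 3 and without IP replicate 2 or 3, and the tanycyte count was 1 without input replicate 3 or IP replicate 2. In limma's camera the adjusted p was 0.00116 for blood, 0.00356 for endothelial, 0.000845 for mural, 0.0116 for leptomeningeal, 0.0242 for ependymal and 0.57 for tanycyte markers. With an estimated correlation it became adjusted p = 0.38 for blood, 0.47 for endothelial, 0.19 for mural, 0.48 for leptomeningeal and 0.55 for ependymal markers. The ependymal list did not pass camera without both libraries of replicate 2 (adjusted p = 0.059).

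Part of the GABAergic and of the pan-neuronal list was higher in IP, and 1 glutamatergic marker was. Of 13 GABAergic markers 5 rose and 0 fell in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), with a median log2 fold change of 0.52. Slc32a1, the vesicular GABA transporter (chromosome 2, 158452687 to 158457668), rose by 0.97 ± 0.18 (SE, adjusted p = 0.00518, edgeR's quasi-likelihood test). Gad1, which makes GABA, rose by 0.92 ± 0.17 (SE, adjusted p = 0.00492, edgeR's quasi-likelihood test), and Gad2, the gene of the second GABA-making enzyme, stood at 0.21 ± 0.13 (SE, adjusted p = 0.27, the same test). The transcription factors Dlx1 and Isl1, which act in the development of inhibitory neurons, rose by 1.68 ± 0.22 and 1.07 ± 0.13 (SE). Dlx1 overlaps its antisense gene and Gad1 overlaps another, and reads of the partners cannot be told apart without strand information. With the block, 6 GABAergic markers rose and 2 fell. Of 12 glutamatergic markers 1 rose, Otp, at 0.84 ± 0.19 (SE), and 1 fell, Foxb1, at -2.32 ± 0.62 (SE), with a median of -0.39, and 2 fell with the block, Foxb1 and Neurod6. Slc17a6, the main vesicular glutamate transporter of the hypothalamus, stood at 0.14 ± 0.39 (SE, adjusted p = 0.82, edgeR's quasi-likelihood test). After length and GC correction with the block Slc17a6 and Gad2 were both called higher, at 0.42 and 0.44 (adjusted p = 0.030 and 0.043, edgeR). Of 15 pan-neuronal genes 6 rose, including Tubb3 at 0.94 ± 0.17 and Syp at 0.84 ± 0.11 (SE), and 1 fell, Syn1, at -0.41 ± 0.13 (SE). Their median was 0.48, near the GABAergic median of 0.52. A rise of GABAergic markers beyond that of neuronal genes was therefore not shown. After length and GC correction with the block 10 pan-neuronal genes rose and 2 fell. Syn1 did not pass with the block (adjusted p = 0.051, edgeR), while Map2 and Rbfox1 then counted as lower. Adjusted over the list alone, 5 GABAergic markers rose and 0 fell, 1 glutamatergic marker rose and 1 fell, and 7 pan-neuronal genes rose and 2 fell. Otp lost its call without IP replicate 3 (0.76, adjusted p = 0.054, edgeR). Foxb1 lost its call without input replicate 2 or 3 or IP replicate 1 or 3 (adjusted p between 0.052 and 0.088, edgeR), and only 3 pan-neuronal genes rose without input replicate 3, IP replicate 2 or IP replicate 3. Of these fits Syn1 kept its call only without input replicate 1, and it lost it with RLE or upper-quartile factors and without the low-count filter (adjusted p = 0.065, 0.051 and 0.070, edgeR). Without input replicate 1, 2 glutamatergic markers fell, without input replicate 2, 2 pan-neuronal genes fell, and without IP replicate 1, 1 GABAergic marker fell. In limma's camera the adjusted p was 0.00654 for GABAergic, 0.89 for glutamatergic and 0.0342 for pan-neuronal genes, and with an estimated correlation it was adjusted p = 0.63 for GABAergic and 0.42 for pan-neuronal genes. Fry gave the GABAergic list an adjusted p = 0.11. The pan-neuronal list did not pass camera without input replicate 3 (adjusted p = 0.065) or without both libraries of replicate 3 (adjusted p = 0.052). Without both libraries of replicate 3, Gad1, Tubb3, Syp and Otp did not pass either (adjusted p = 0.071, 0.074, 0.057 and 0.11, edgeR). Their log2 fold changes were then 0.999, 1.06, 0.84 and 0.87.

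**Figure D2:**
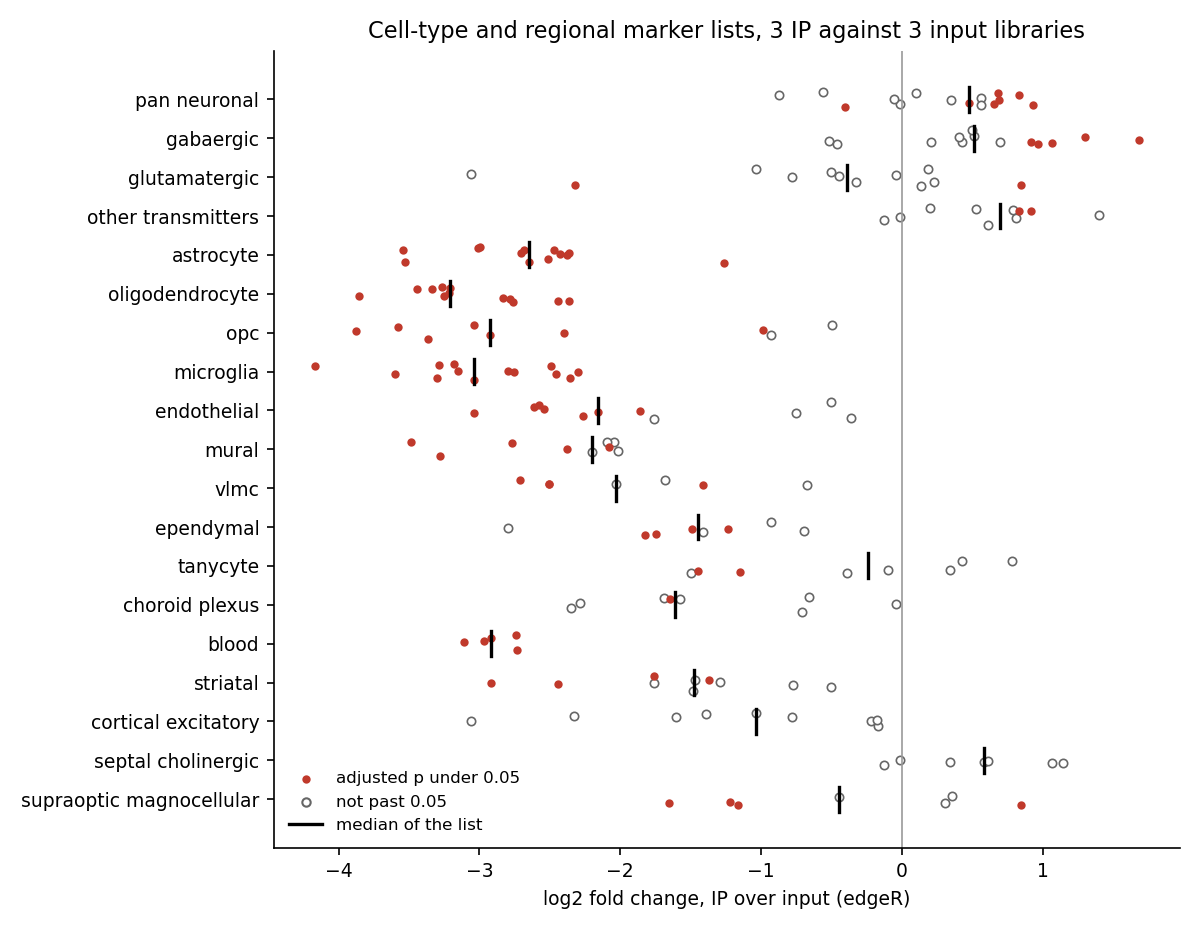
Each point is a marker gene, placed by its log2 fold change of IP over input on the horizontal axis, with one marker list per line, and the black bar is the median of the list. Filled points passed an adjusted p of 0.05 in edgeR's test. The astrocyte, oligodendrocyte and microglial medians lie at -2.65, -3.21 and -3.04, while the GABAergic and pan-neuronal medians lie at 0.52 and 0.48.

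Markers of neighbouring regions varied with the pool of tissue. Of the genes of other transmitters 2 or 3 rose and 0 fell without any one library. Of 10 striatal markers 4 fell, with a median log2 fold change of -1.47, among them Adora2a at -2.92 ± 0.70 and Rgs9 at -1.37 ± 0.40 (SE). With the block, 8 striatal markers fell, and without IP replicate 2 or IP replicate 3 there were 0. The striatal count was 2 without input replicate 1 or 3 and 8 without input replicate 2. Adora2a had 81.6, 15.6 and 34.5 CPM in input replicates 1, 2 and 3. Of 9 markers of cortical excitatory neurons 0 passed in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), with a median of -1.03. Fezf2, Neurod2 and Neurod6 fell with the block, and this list's camera adjusted p was 0.60 without and 0.0396 with the block, and adjusted p = 0.89 with an estimated correlation. Without both libraries of replicate 1, 0 cortical markers fell and the direction in camera turned upward (adjusted p = 0.72, in the fit without the block). Slc17a7, the cortical glutamate transporter, had 363, 103 and 44.0 CPM in input replicates 1, 2 and 3 and 43.3, 190 and 63.5 CPM in IP. Of 7 septal cholinergic markers 0 passed in edgeR's test (1 at an unadjusted p under 0.05 and 1 in DESeq2), with a median of 0.58, and with the block 3 rose and the camera adjusted p went from 0.36 to 0.0489, and adjusted p = 0.87 with an estimated correlation. Without IP replicate 1, 2 septal markers rose. Of 10 genes of other transmitters 2 rose, the dopamine synthesis genes Th at 0.92 ± 0.20 and Ddc at 0.83 ± 0.18 (SE). Without both libraries of replicate 3 neither passed (1.07 and 0.84, adjusted p = 0.093 and 0.12, edgeR). The camera adjusted p of this list was 0.0922 without and 0.029 with the block, and adjusted p = 0.50 with an estimated correlation. Of 7 supraoptic magnocellular genes 1 rose (Otp) and 3 fell, the vasopressin gene Avp at -1.65 ± 0.32, the oxytocin gene Oxt at -1.22 ± 0.35 and Caprin2 at -1.17 ± 0.25 (SE), and the list's camera adjusted p was 0.59. Without input replicate 3 only 1 supraoptic gene fell, as Oxt and Caprin2 lost their calls, and Otp lost its call without IP replicate 3. Oxt also lost its call without input replicate 2 or IP replicate 1 or 2. When adjusted over the list alone, 8 striatal, 0 cortical and 0 septal markers, 2 genes of other transmitters and 1 and 3 supraoptic genes (higher and lower) passed. Adora2a lost its call without IP replicate 2 or 3, and Rgs9 without input replicate 1 or 3 or IP replicate 2 or 3. For striatal markers the camera adjusted p was 0.0258, and adjusted p = 0.76 with an estimated correlation, 0.053 without input replicate 1 and 0.064 without IP replicate 2.

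The peptide genes higher in IP included several that are known from preoptic neurons. Of 38 neuropeptide precursor genes tested 12 rose and 2 fell, with a median log2 fold change of 0.76. Adjusted over the list alone 13 rose and 2 fell. Pnoc, whose Cre driver marks the tagged cells, is a member and stayed in these counts and in the list's tests. After length and GC correction with the block the median was 0.54, against 0.51 for pan-neuronal genes. A rise of peptide genes beyond that of neuronal genes was therefore not shown. Among those that rose, the largest folds were those of Gnrh1, the precursor of gonadotropin-releasing hormone, Pnoc, Npy (neuropeptide Y), Ghrh (growth hormone-releasing hormone), Sst (somatostatin) and Gal (galanin). Gnrh1 had 9.05 ± 1.33 CPM in IP against 1.29 ± 1.02 CPM in input (SD, n = 3), a log2 fold change of 2.80 ± 0.62 (SE). Ghrh rose by 1.80 ± 0.37 (SE), a 3.49-fold difference. Sst (chromosome 16, 23708323 to 23709708) had 545 ± 146 against 163 ± 25.3 CPM (SD, n = 3), a 3.35-fold difference with an adjusted p of 0.000836 in edgeR's test. Gal (chromosome 19, 3459915 to 3464544) had 56.7 ± 16.1 against 18.7 ± 8.31 CPM (SD, n = 3), a 3.03-fold difference. Npy had 264, 45.0 and 60.4 CPM in IP replicates 1, 2 and 3, and its log2 fold change of 2.05 ± 0.63 (SE) became 0.84 without IP replicate 1. After length and GC correction Npy did not pass (1.22, adjusted p = 0.21, edgeR). With correction and block Npy, Gal, Ghrh and Tac2 passed at 0.90, 1.001, 1.12 and 0.88, and Avp and Oxt at -2.57 and -2.12. Cartpt, Trh, Nts, Tac2, Calca and Tac1 also rose, by 1.57, 1.38, 1.39, 1.45, 1.47 and 0.98. Avp and Oxt were the 2 that fell. Vip stood at 1.53 ± 0.82, Cort at 3.13 ± 1.35 and Cck at 0.97 ± 0.37 (SE) without the block and did not pass. With the block they stood at 1.07, 3.26 and 0.92 and passed (adjusted p = 0.0114, 0.00506 and 0.0203, edgeR). Cck also passed in DESeq2 (adjusted p = 0.00901), without the low-count filter (adjusted p = 0.0342, edgeR) and without both libraries of replicate 1 (1.40, adjusted p = 0.0123, edgeR).

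Several of these peptide calls were lost when 1 library was left out. Gnrh1 and Calca lost theirs without input replicate 3 (2.82 and 1.45, adjusted p = 0.051 and 0.054, edgeR). Gal, Nts and Tac2 lost theirs without IP replicate 3 (1.41, 1.28 and 1.43, adjusted p = 0.055, 0.053 and 0.053, edgeR). Npy lost its call without input replicate 2 or 3 or IP replicate 1, Tac1 without input replicate 2 or 3 or IP replicate 1 or 3, and Oxt without input replicate 2 or 3 or IP replicate 1 or 2. Pnoc, Ghrh, Sst, Cartpt, Trh and Avp kept theirs without any one library. Without both libraries of replicate 3, however, Ghrh, Cartpt, Trh and Avp did not pass (adjusted p = 0.10, 0.067, 0.093 and 0.055, edgeR), and Avp did not without replicate 2 (adjusted p = 0.060, edgeR). The list's camera adjusted p was 0.000369, and adjusted p = 0.48 with an estimated correlation. Of 12 genes that process or store peptides 4 rose and 2 fell, or 5 and 3 adjusted over the list alone, among them Chga at 1.01 ± 0.21 and Scg5 at 0.98 ± 0.15 (SE) upward and Scg3 at -0.76 ± 0.14 (SE) downward. Without input replicate 3, IP replicate 1 or IP replicate 2 only 2 of them rose, and without any of these or IP replicate 3 only 1 fell. The camera adjusted p of that list was 0.15.

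**Figure D3:**
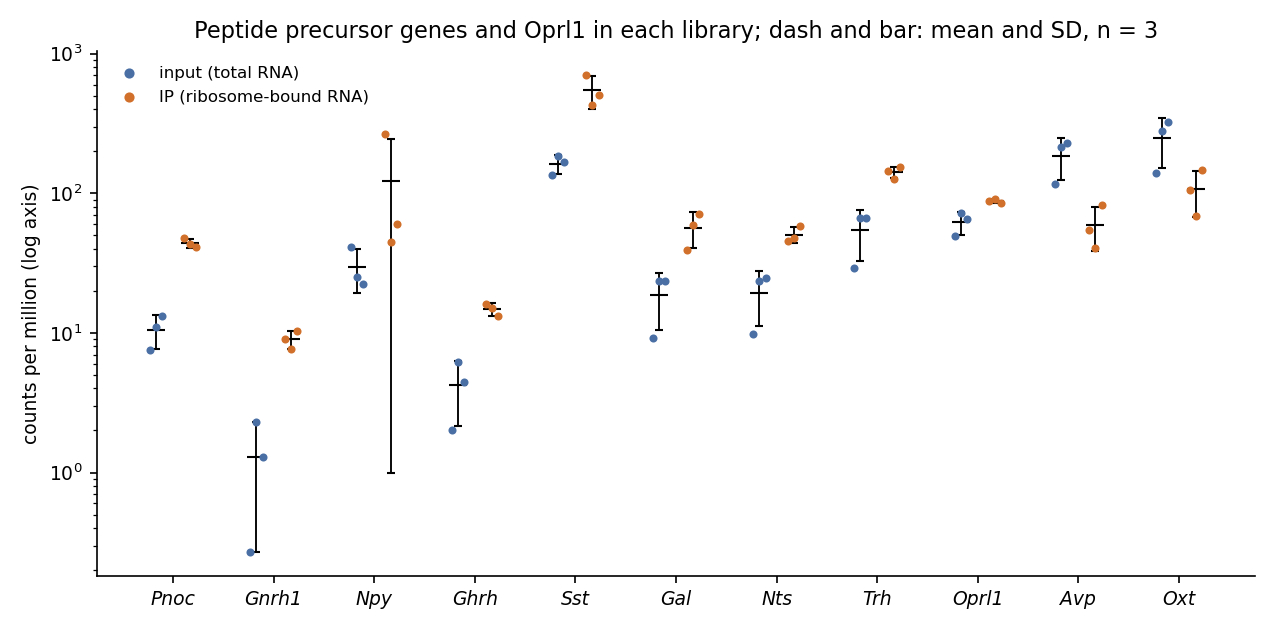
Points are the CPM of each library on a log axis for 10 peptide precursor genes and for Oprl1, the nociceptin receptor gene, with the mean and SD of 3 libraries as dash and bar. All 3 IP libraries lie above all 3 input libraries for Pnoc (41.1 to 47.7 against 7.51 to 13.2 CPM), and Avp and Oxt lie lower in IP on average.

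For receptors and markers of preoptic thermoregulatory neurons the number of calls varied with the fit. Of 20 such markers 1 rose, the heat-sensing channel gene Trpm2, at 0.72 ± 0.18 (SE), and 1 fell, Il1rap, at -1.97 ± 0.35 (SE), and with the block 3 rose, adding Esr1 and Opn3. Esr1, the oestrogen receptor alpha gene, stood at 0.76 ± 0.27 and Opn3 at 0.93 ± 0.69 (SE), with adjusted p of 0.0651 and 0.35 without and 0.0123 and 0.00278 with the block (edgeR). Ptger3, the prostaglandin receptor of fever, stood at -1.11 ± 0.46, Lepr at -1.57 ± 0.81, Bdnf at 0.01 ± 0.30 and Adcyap1 at 0.46 ± 0.16 (SE), and none of these 4 passed. Adcyap1 passed with RLE factors (adjusted p = 0.0495, edgeR), in DESeq2 (adjusted p = 0.041) and after length and GC correction (0.83, adjusted p = 0.00496, edgeR). Lepr had 0.26 CPM in IP and 0.79 CPM in input. Of 48 hormone and peptide receptor genes 3 rose (the substance P receptor gene Tacr1 and the somatostatin receptor genes Sstr3 and Sstr2, the latter pair at 0.95 and 0.79) and 3 fell (Ntsr2, Ghr and Sstr1, at -2.73, -1.04 and -1.47), and with the block 6 rose, adding Esr1, Ntsr1 and Thra, and 5 fell, adding Thrb and Vipr1. Of 4 opioid receptor genes 1 rose, Oprl1, the receptor of nociceptin, with 88.1 ± 2.72 CPM in IP against 62.2 ± 11.6 CPM in input (SD, n = 3), a log2 fold change of 0.50 ± 0.16 (SE, adjusted p = 0.0435, edgeR's quasi-likelihood test). Of the fits with 1 library left out that call held only without input replicate 2, and the adjusted p lay between 0.0552 and 0.12 without any other library. It was also lost with upper-quartile factors (0.49, adjusted p = 0.059, edgeR) and with library totals alone (0.40, adjusted p = 0.096, edgeR). Trpm2 lost its call without input replicate 3 or IP replicate 2. Without input replicate 2, 2 thermoregulatory markers rose and 1 opioid receptor gene fell. Without IP replicate 3, 1 hormone receptor gene rose. Tacr1 lost its call without IP replicate 3, Sstr2 without input replicate 2 or 3 or any IP library, after length and GC correction (0.64, adjusted p = 0.11, edgeR) and with library totals alone (0.69, adjusted p = 0.060, edgeR), and Sstr1 without input replicate 1 or 3 or IP replicate 1 or 3. Adjusted over the list alone, 1 thermoregulatory marker rose and 1 fell, 2 hormone receptors rose and 2 fell, and 1 opioid receptor rose. DESeq2 called 4 thermoregulatory markers and 7 hormone receptors higher, and after length and GC correction with the block edgeR called 5 and 8. The camera adjusted p was then 0.0467 and 0.0901, against 0.38, 0.60 and 0.87 for these 3 lists without correction or block. With an estimated correlation, run without correction or block, the thermoregulatory list had a camera adjusted p = 0.61. The hormone receptor mean (-0.03) differed in sign from its median (0.03).

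Without a correction for transcript length and GC, ion channel and transmitter receptor genes went both ways. Of 27 potassium channel genes 4 rose and 2 fell, with Kcnk3 at 1.17 ± 0.18 and Kcna1 at -2.60 ± 0.50 (SE), and 6 and 5 with the block. Of 19 calcium, sodium and HCN channel genes 2 rose and 2 fell, with Hcn3 at 0.85 ± 0.19 and Scn3a at -0.95 ± 0.18 (SE), and 4 and 3 with the block. Of 16 GABA receptor genes 2 rose, Gabbr1 at 0.56 ± 0.15 and Gabre at 0.67 ± 0.20 (SE), and 1 fell, Gabrb2, at -3.24 ± 0.56 (SE), and 3 rose with the block. Of 22 glutamate receptor genes 1 rose, Grin2d, at 0.63 ± 0.16, and 1 fell, Grm3, which astrocytes also express, at -2.51 ± 0.27 (SE), and 6 rose and 2 fell with the block. Of 26 monoamine receptor genes 2 rose, Hrh3 at 0.87 ± 0.15 and Htr7 at 0.70 ± 0.22 (SE), and 1 fell, Adra1a, at -1.48 ± 0.38 (SE), and with the block 3 rose and 4 fell. The counts adjusted over the list alone were, as higher and lower, for potassium channels 4 and 2, for the second channel list 2 and 2, for GABA receptors 1 and 1, for glutamate receptors 0 and 1 and for monoamine receptors 1 and 0. Gabbr1 lost its call without input replicate 1 or 3 or IP replicate 2 or 3, Gabre without input replicate 1 or 3 or IP replicate 1 or 3, and Grin2d without any one IP library. Grin2d also lost its call after length and GC correction (0.44, adjusted p = 0.20, or 0.49, adjusted p = 0.060 with the block, edgeR). Scn3a lost its call where the correction set the mean change to 0 (-0.28, adjusted p = 0.12, or -0.28, adjusted p = 0.14 with the block, edgeR). Without both libraries of replicate 3, Scn3a, Kcnk3, Kcna1, Hcn3, Gabrb2 and Hrh3 did not pass (adjusted p between 0.067 and 0.14, edgeR). Their log2 fold changes were then -1.06, 1.18, -2.61, 0.79, -3.18 and 0.84. With library totals alone Gabbr1, Gabre and Htr7 did not pass (adjusted p = 0.0504, 0.070 and 0.070, edgeR), nor did Htr7 with upper-quartile factors (adjusted p = 0.052, edgeR). Htr7 lost its call without input replicate 1 or 3 or any IP library, and Adra1a without input replicate 1 or 3 or IP replicate 2 or 3. Without input replicate 2, 4 monoamine receptor genes fell and 2 glutamate receptor genes fell. Without input replicate 1, 4 genes of the second channel list and 2 glutamate receptor genes rose. That channel list had 1 higher gene without IP replicate 3 and 1 lower gene without input replicate 3, IP replicate 2 or IP replicate 3, and 1 potassium channel gene fell without IP replicate 3. Hrh3, Kcnk3, Hcn3 and Grin2d each overlap another gene, so that their read counts are uncertain. DESeq2 called 4 genes of the second channel list and 3 glutamate receptor genes higher, and 2 glutamate and 3 monoamine receptor genes lower. The camera adjusted p was 0.57, 0.60, 0.68, 0.59 and 0.77 for the 5 lists in this order. After length and GC correction with the block it was 0.0543, 0.0317, 0.00936, 0.0317 and 0.70, upward in each, with 10, 8, 6, 5 and 3 genes higher and 3, 2, 1, 1 and 6 lower. The GABA receptor list also passed after the correction without the block (adjusted p = 0.0192, camera). An estimated correlation was run only without correction or block. It gave camera adjusted p = 0.87 for the second channel list, 0.87 for GABA receptors and 0.83 for glutamate receptors. Of 24 regional transcription factor genes 2 rose, Lhx6, with a mean of 60.7 CPM in IP and 30.3 CPM in input, and Zic1, at 0.77 ± 0.22 (SE), and 3 fell, Tshz2 at -1.13 ± 0.29, Nkx6-2 at -2.48 ± 0.34 and Nkx2-2 at -2.30 ± 0.28 (SE), the latter pair being genes that oligodendrocytes also use. These counts were 2 and 3 adjusted over the list alone, with the block 6 and 4, and without IP replicate 1 or IP replicate 3 none of this list rose. Zic1 lost its call with library totals alone (adjusted p = 0.053, edgeR) and without input replicate 3 or any IP library, and Lhx6 without input replicate 1 or 3 or IP replicate 1 or 3. Tshz2 lost its call without input replicate 2 or 3 or IP replicate 3 (adjusted p between 0.0568 and 0.0805, edgeR). The list's camera adjusted p was 0.90. Median and mean or test differed in sign for the regional transcription factor, monoamine, GABA and glutamate receptor and potassium channel lists.

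Transcripts of the mitochondrial genome and nuclear long RNAs were depleted in IP. Mitochondrial transcripts took 0.15% ± 0.06 of counts in IP against 4.35% ± 0.75 in input (SD, n = 3), and all 15 tested fell, with a median log2 fold change of -5.73. The lowest of the protein-coding genes, mt-Nd5 (positions 11742 to 13565 of the mitochondrial genome), had 24.0 ± 5.88 CPM in IP against 2737 ± 420 CPM in input (SD, n = 3), a 114-fold difference. Of 10 long RNAs known mainly from the nucleus 7 fell and 1 rose, with a median of -2.81, and Meg3 stood at -4.29 ± 0.25 and Snhg11 at -2.65 ± 0.12 (SE), while Peg13, which lies within Trappc9, rose by 0.81 ± 0.12 (SE). Of 41 ribosomal protein genes 22 rose and 0 fell in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), with a median of 0.53, led by Rplp2 at 0.89 ± 0.16 and Rpl8 at 0.75 ± 0.14 (SE). After length and GC correction with the replicate block 14 of them rose and 4 fell, with a median of 0.13 and a camera adjusted p of 0.0255, and Rpl8 stood at 0.18 (adjusted p = 0.20, edgeR). Rplp2 did not pass after the correction without the block (0.35, adjusted p = 0.074, edgeR). Fry gave the list an adjusted p = 0.11. Many ribosomal protein genes have near-identical pseudogenes, so that single values are uncertain. The ribosomal count was 16 without input replicate 1, 8 without input replicate 3, 12 without IP replicate 1 and 6 without IP replicate 3. Of 7 histone genes 4 fell, with H1f2 at -1.85 ± 0.32 and H2bc4 at -1.41 ± 0.26 (SE), and 1 rose, H1f0, at 0.43 ± 0.12 (SE), which is not a replication-dependent histone. H1f0 lost its call with library totals alone (adjusted p = 0.071, edgeR) and without input replicate 3 or any IP library, and 2 histone genes fell without any one library but input replicate 2. Adjusted over the list alone, 15 mitochondrial genes fell, 7 long RNAs fell and 1 rose, 26 ribosomal protein genes rose, and 4 histone genes fell and 1 rose. Camera gave an adjusted p of 2.10e-16 for mitochondrial genes, 0.000369 for long RNAs, 8.01e-10 for ribosomal proteins and 0.36 for histones. With an estimated correlation it was adjusted p = 0.20 for mitochondrial genes, 0.18 for long RNAs and 0.61 for ribosomal proteins.

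Few activity-dependent and stress genes passed without the block. Of 16 immediate early genes, whose median log2 fold change was -0.64, 1 rose, Ier2, at 0.97 ± 0.23 (SE), and 0 fell in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), and with the block 5 fell (Arc, Npas4, Nr4a1, Homer1 and Egr3). Without both libraries of replicate 1, in the fit without the block, 2 rose and 1 fell, and the direction in camera turned from lower to higher (adjusted p = 0.84). Ier2 lost its call without IP replicate 2 and after length and GC correction (0.51, adjusted p = 0.10, or adjusted p = 0.12 with the block, edgeR). Of 10 genes of the stress response to tissue handling 0 passed in edgeR's test (2 at an unadjusted p under 0.05 and 0 in DESeq2), among them Hspa8 at 0.40 ± 0.15 and Hsp90aa1 at 0.29 ± 0.11 (SE), and with the block 1 rose (Hspa8, adjusted p = 0.0315, edgeR) and 1 fell (Hmox1). Without input replicate 2, 1 stress gene rose. Among these lists 1 immediate early gene rose and 0 stress genes passed when adjusted over the list alone. The camera adjusted p was 0.90 for the immediate early list and 0.60 for the stress list.

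Over all genes, the protein-coding genes with the largest rise at a mean of at least 3 log2 CPM, after Pnoc and Npy, were Pvalb, Lbhd2, Lars2, Crabp1, Coq7, Sst, Ndufa4 and Atpif1. Pvalb, the parvalbumin gene (chromosome 15, 78075314 to 78090600), had 459 ± 46.8 CPM in IP against 112 ± 46.8 CPM in input (SD, n = 3), a 4.08-fold difference. Crabp1, which binds retinoic acid in the cytosol, rose by 1.77 ± 0.30, Coq7, an enzyme of coenzyme Q synthesis, by 1.75 ± 0.28 and Ndufa4, a respiratory chain gene, by 1.72 ± 0.17 (SE). Lars2 rose by 1.85 ± 0.29 (SE), but carries a stretch that resembles ribosomal RNA, and its value is uncertain. The 10 largest falls were all transcripts of the mitochondrial genome. By adjusted p, the first 5 genes upward were Sncb, Polr2h, Chchd2, Eid2 and Sult4a1, led by the beta-synuclein gene Sncb at 1.36 ± 0.12 (SE, adjusted p = 0.000222, edgeR's quasi-likelihood test), and the first 5 downward were mt-Nd5, Mal, Gjc3, Anln and Hepacam. All of these genes but Npy kept their call without any one library. Without both libraries of replicate 3, Pvalb, Lbhd2, Coq7 and Atpif1 did not pass (adjusted p = 0.065, 0.095, 0.053 and 0.093, edgeR). Their log2 fold changes were then 2.07, 2.10, 1.85 and 1.54. Lbhd2 did not pass after length and GC correction either (0.93, adjusted p = 0.095, or 0.76, adjusted p = 0.080 with the block, edgeR), and with correction and block Crabp1, Ndufa4 and Atpif1 stood at 0.996, 1.07 and 0.995. Polr2h overlaps Clcn2, Chchd2 overlaps Phkg1, Hcn3 overlaps Pklr and mt-Nd5 overlaps mt-Nd6, so that the share of reads given to each is uncertain.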

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

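The alternatives that left out both libraries of a pool, used library totals alone or corrected for transcript length and GC were chosen after seeing the data. Against 2400 higher and 3191 lower genes, a test against a fold change of 1.5 called 448 and 1656. Leaving out 1 library or 1 pool gave 133 to 2630 higher and 742 to 3080 lower genes. Both lowest values came without replicate 3, where 72 calls of named genes were lost. Where log2 fold changes are given above for that fit, they lay near those of the main test. Without replicates 1 and 2 the counts were 2041 and 2808, and 1508 and 2095, and the cause of the difference was not tested. DESeq2 called 2905 and 3781. A length and GC correction called 2381 and 3128 with the mean change kept. With the mean change set to 0 it called 4620 higher and 2326 lower genes, and 5295 and 2649 with the replicate block; this setting moved the median log2 fold change by 0.26, library totals alone moved it by -0.11, and a shift upward raises the higher count by construction. In that setting with the block, Slc5a7, Pgr and Prlr had 0.58, 0.53 and 0.76, against -0.01, -0.05 and -0.04. Pcsk1, at -0.52, had 0.18 in that setting with the block and 0.18 without it. The cause was not tested beyond the shift. The neuropeptide list did not pass camera in that setting without the block (adjusted p = 0.073). Pnoc kept its direction and call under every alternative run for it, at 1.80 to 2.30, which leaves out the test against a fold change of 1.5.

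Of 36 gene lists, 16 passed camera, 0 did with an estimated correlation and 25 with the correction that sets the mean change to 0 and the block. The replicate block called 2838 higher and 3617 lower genes and 20 lists, adding other transmitters, choroid plexus, cortical and septal markers. Among named genes it added 29 calls and removed that of Syn1, and it changed no other call of a named gene or list. Fry did not call the GABAergic, striatal and ribosomal protein lists. The pan-neuronal list lost its call without input replicate 3 or replicate 3 as a whole, the striatal list without input replicate 1 or IP replicate 2, and the ependymal list without replicate 2. DESeq2 added 9 calls of named genes and removed those of Syn1 and Clic6. No called gene named by the rule changed sign when a library was left out.

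Of the 10 divisions of the 6 libraries into 3 and 3, 1 called as many genes as the real one, which is itself, with 5591 against at most 0 in the others (up to 882 at an unadjusted p under 0.05, edgeR). For camera, 4 divisions called at least as many lists as the real 16, and the highest other called 19. Of the 3 others that part all 3 pairs, each called 0 genes and 5 to 16 lists, and the 6 remaining ones part 1 pair and mix the pools. The divisions are too few for a share under 0.05. Each one but the real one holds both kinds of library on each side in unequal number. Part of the difference between IP and input therefore remains in all of them, and their calls do not measure chance.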

Other observations

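The gene families and lists of this part, and all tests in it, were chosen after the results were seen. Genes of energy metabolism encoded in the nucleus were higher in IP. Of 90 nuclear respiratory-chain genes 71 rose and 0 fell in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), with a median log2 fold change of 1.01, among them Ndufa4 at 1.72. Of 77 mitochondrial ribosome genes 52 rose and 0 fell (again 0 unadjusted and 0 in DESeq2), with a median of 0.72, and of 45 proteasome genes 19 rose and 2 fell. After length and GC correction with the block, 56 respiratory-chain genes rose and 3 fell, with a median of 0.57, and 50 mitochondrial ribosome genes rose and 1 fell, with a median of 0.48. The proteasome count was 10 without input replicate 3, 11 without IP replicate 1 or 2 and 12 without IP replicate 3. With limma's camera at an estimated correlation none of these 3 families passed (adjusted p = 0.39 for each). Chromatin regulators went the other way, with 22 of 62 lower and 2 higher and a median of -0.44, as did zinc finger (Zfp) genes, with 82 of 367 lower and 19 higher and a median of -0.33, where 3191 of all 18640 genes tested were lower. After length and GC correction with the block 57 Zfp genes were lower and 30 higher, with a median of -0.089, and 18 chromatin regulators were lower and 6 higher, with a median of -0.26. For these the camera adjusted p was 0.00188 and 0.00328, and adjusted p = 0.51 and 0.39 with an estimated correlation. With correction and block it was 0.026 and 0.64. The lower chromatin count was 10 without input replicate 3 or IP replicate 3, 12 without IP replicate 2, and the higher count 1 without input replicate 3 or IP replicate 2 and 0 without IP replicate 1. The lower Zfp count was 43 without input replicate 3, 42 without IP replicate 2 and 51 without IP replicate 3, and the higher one 11, 9 and 12 without input replicate 3, IP replicate 3 and IP replicate 1.

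Genes known from the thalamus, which borders the hypothalamus, were called in part when the pools were compared within themselves. Of 13 such genes 0 passed in edgeR's test without the block (0 at an unadjusted p under 0.05 and 0 in DESeq2), and 9 rose with it. In limma's camera this list had an adjusted p = 0.20 without the block, 3.15e-06 with it and 0.71 with an estimated correlation. Tnnt1 had 18.4, 219 and 78.0 CPM in IP replicates 1, 2 and 3 against 3.52, 66.9 and 20.1 CPM in input. Of 14 genes of the interneuron class that includes somatostatin and parvalbumin cells 6 rose and 1 fell, or 8 and 2 with the block. Of these, 3 rose without input replicate 3 or IP replicate 1, 3 fell without IP replicate 1, and 0 fell without input replicate 3 or IP replicate 3. Ttr, the main transcript of choroid plexus, had 30.4, 19.9 and 382 CPM in input replicates 1, 2 and 3 and 8.40, 3.36 and 72.9 CPM in IP.

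Pool 1 differed from the other pools. In input replicate 1, 49 genes with a mean above 3 log2 CPM lay more than 4-fold from the mean of the other inputs, against 17 in input replicate 2 and 4 in input replicate 3, and Neurod6, below that mean, had 58.6 CPM there against 0.72 and 1.57. An exchange of IP and input in this pool is argued against by the 0.11% of mitochondrial counts in the library labelled IP replicate 1, and a difference in depth by a ratio of 1.08 between the highest and lowest input total. Of the 49 genes 98.0% lay on the same side in IP replicate 1, which is what a different share of neighbouring tissue in the punches may give. The exception was Slc17a7, the cortical glutamate transporter gene. It was higher in input replicate 1 but lower in IP replicate 1 than in the other IP libraries. The share was not computed for the other pools, so it has no baseline. Other differences between the animals of the pools stay open and were not tested.

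Slc17a6, the glutamate transporter gene, stood near its input level in IP (0.14 ± 0.39, SE) while glial markers fell, and was called higher after length and GC correction with the block (0.42, adjusted p = 0.030, edgeR). Carry-over of tissue RNA at the rate of glial RNA is argued against, since Slc17a6 lay 2.95 above the median of 38 glial markers on the log2 scale, whose SD was 0.54. Carry-over from other neurons cannot be told apart from expression in tagged cells, because 4 of 19 striatal and cortical markers reached the lower 95% bound of Slc17a6 (-0.63), although their median was -1.39. Without any one library Slc17a6 lay between -0.18 and 0.56. That some tagged cells express Slc17a6 is a hypothesis that the libraries of pooled tissue leave untested.

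For the respiratory-chain genes, short transcripts were a technical candidate, since the log2 fold change fell with transcript length across genes (Spearman -0.28; genes are not independent replicates). Of 10000 random lists matched on length, GC and expression, 0 reached the median of the 90 genes (1.01, against a median of 0.57 and a highest value of 0.75 in the random lists). Each match was drawn on its own, so the random lists leave out correlation within the family, which was chosen after its values were seen. The count of 0 is therefore no measure of chance. The matched lists leave part of the median unmatched, and these properties may be a large part of it. Mitochondria bound to the beads are argued against by the median of -5.73 of mitochondrially encoded transcripts. Loss of glial RNA alone stays open: after length and GC correction with the block the median lay 0.0588 above that of pan-neuronal genes (0.57 against 0.51, permutation test, p = 0.61). A higher demand for respiration in the tagged cells could also give this pattern and was not tested.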
